A study of Mus musculus with 6 samples.

How the data were processed

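Gastrocnemius muscle of male C57BL/6J mice was profiled on 6 expression arrays, 1 for each combination of 3 diets and 2 fasting times. Per the labels, total RNA was extracted with a kit for fibrous tissue, samples were pooled within each group, and biotinylated cRNA was made with a 3' IVT kit. The labels give an age of 21 months, whereas a start at 6 weeks of age and 15 weeks of diet give a younger age; no result here uses the age. How many animals entered a pool is not given in the sources used here.

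The deposited values are intensity on a linear scale, 1 per probe set and array. They were made with MAS5, per the submitters' processing notes, and its version and settings are not given in the sources used here. The mean after removing the lowest and highest 2% of probe sets was 500.004 on every array, which shows that each array had been scaled to a common level. The median signal ran from 63.2 to 69.7 between arrays and the share of non-control probe sets above the floor from 68.9% to 71.6%. The 3' to 5' signal ratio of the actin control probe sets was 1.08 to 1.52, highest in the HF pool at 4 h, and that of GAPDH 0.814 to 0.863. No detection calls were used, and the number of arrays limits the precision.

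Of 45101 probe sets, 64 controls were left out. Among the 45037 others, 34945 had 1 gene symbol in the platform annotation, 932 several and 9160 none listed, and only those with 1 symbol were named. Symbols were updated through the gene identifier for 34741 probe sets. The probe set with the highest mean log2 signal represented each of 18193 genes. Signals under the 30th percentile (26.4) were set to that floor before log2, which applied to 96 values in 92 of the genes kept. A gene was kept when its mean log2 signal exceeded the median over non-control probe sets (5.88), which left 11526 genes, 7147 of them with more than 1 probe set. A fold against a pool at the floor is given as a lower bound.

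An additive model of diet and fasting time was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 2 residual degrees of freedom and 7.27 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg at 0.05. Fasting was blocked by diet and each diet contrast by fasting time. Genes at least 1.5-fold apart the same way in every pair of pools, and at least 2-fold apart in single pairs, were counted without a test. Correlations across genes treat genes as a description of the arrays. Comparisons that share arrays were set beside 100 simulations of pools without effects.

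The 40 gene lists, the groups, the model, the rule for named genes and the alternatives were fixed before the data were examined. Lists with at least 3 measured members were tested, which left 37; the neutrophil, erythroid and keratinocyte lists had 2 measured members each. Camera with a preset correlation of 0.01 was the test, with camera using an estimated correlation and fry beside it, adjusted over all lists within a contrast. For single pairs of pools, list medians were set among 10000 random lists matched on signal in 20 bins. The named genes are the 12 highest and 12 lowest differences among genes past the threshold with the same sign in every pair. Where fewer passed, the largest smallest-pair differences with both pools above the floor filled the places. In addition, 2 to 4 members of each list described and 18 genes fixed in advance are named. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 drew the figures.

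The fit was tested on simulated data over 11526 genes in 20 draws with 200 changed genes each. With spreads as observed, 9.09% of calls were false for fasting, 8.51% for HF against Control and 8.11% for HF+SFC+ALA against HF, and with spreads drawn from the prior 4.51%, 4.02% and 4.67%. With observed spreads, 2-fold changes were recovered in 86.1%, 79.2% and 80.5% of genes in the same order, and 1.5-fold changes in 66.1%, 52.8% and 52.8%. Recovery was lower with spreads drawn from the prior, at 73.9%, 64.6% and 63.9% for 2-fold and 48.8%, 29.5% and 30.5% for 1.5-fold changes. With observed spreads and no changed gene, 13, 12 and 15 of 20 draws had at least 1 call, with up to 8, 7 and 9 calls. With spreads drawn from the prior, 2, 0 and 1 of 20 draws had a call, with up to 2, 0 and 1 calls. A simulated list of 15 members shifted by 0.3 for HF against Control was found in 20 of 20 draws by camera with the preset correlation, 2 by fry and 0 with an estimated correlation. Genes in these draws were independent, which suits the preset correlation. In the data the estimated correlation was 0.53 for fatty acid oxidation, 0.26 for collagen and matrix and 0.03 for adipocyte markers. The draws therefore do not show how the preset test behaves with correlated genes.

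Alternatives were quantile normalization, no filter on signal, a filter at the 65th percentile, no floor, a pseudocount equal to the floor, the mean over the probe sets of a gene, eBayes without the trend, fasting without diet in the model, and each array left out in turn.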

Results

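Transcript levels were measured on 6 expression arrays of gastrocnemius muscle from male C57BL/6J mice. From 6 weeks of age the mice ate 1 of 3 diets for 15 weeks. The Control diet held 10 kcal% fat and the high-fat diet (HF) 60 kcal% fat. The HF+SFC+ALA diet was the high-fat diet with sodium ferrous citrate (SFC), an iron salt, at 0.023% by weight and 5-aminolevulinic acid phosphate (ALA), a precursor of heme, at 0.2% by weight. Each diet was sampled after 4 h and after 24 h without food, and each of these 6 combinations was 1 array hybridised with RNA pooled within the group. No combination had replicates, so every fasting time had 3 pools and every diet 2. The p-values of single genes rest on the spread between pools left after diet and fasting time are taken out. This spread holds biological and technical differences between pools and any difference in the fasting response between diets. It is drawn towards that of other genes of like signal (7.27 prior against 2 residual degrees of freedom). Camera with the preset correlation instead sets the members of a list against the other genes. Its p-values therefore do not measure the spread between pools alone. The small number of arrays limits the precision of every value. The series asks how an iron salt with a heme precursor bears on muscle and its mitochondria during high-fat feeding. In all comparisons 11526 genes were tested, log2 differences carry the standard error of the fit over 6 pools, and genes within a pool are not independent of each other.

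The first comparison set 24 h of fasting against 4 h. Acot1 and Acot2, which encode thioesterases that split fatty acyl-CoA, rose 2.74-fold (log2 difference 1.45 ± 0.21, adjusted p = 0.0114) and 2.16-fold (1.11 ± 0.08, adjusted p = 0.00106). Tfrc, the transferrin receptor that takes up iron, fell 2.62-fold (-1.39 ± 0.09, adjusted p = 0.000651). Its signal was 4112, 3192 and 3368 at 24 h in the Control, HF and HF+SFC+ALA pools against 10076, 10053 and 7826 at 4 h. Hp, which encodes the hemoglobin-binding protein haptoglobin, fell 3.07-fold (-1.62 ± 0.31, adjusted p = 0.0337), with -1.47 in Control, -0.61 in HF and -2.77 in HF+SFC+ALA. Adipoq, an adipocyte gene fixed in advance, stood at -0.68 ± 0.17 without passing (adjusted p = 0.0838). Its differences of -0.64, -0.12 and -1.29 ordered the diets as those of Hp did. Whether the fall of Hp follows adipocyte RNA in the pools was not tested. Ppargc1a, a coactivator of mitochondrial biogenesis, fell in all 3 diets (differences of -1.61 to -0.48 between pools, adjusted p = 0.0212). Fbxo32, a ubiquitin ligase of muscle wasting, rose by 0.84 ± 0.07 (adjusted p = 0.00146). Tnfrsf19, Bcl2l11 (a promoter of apoptosis), Neat1 (a long noncoding RNA), Zc3h6, Btnl9, Gins1, Dixdc1, Acss1, Srcap and Ccrl2 also rose, by 0.90 to 1.37. Of the other probe sets above the signal filter, that of Acss1 went the opposite way, at -0.67, and that of Srcap gave 0.33, while those of Tnfrsf19 gave 0.23 and 1.06 and those of Bcl2l11 0.47 and 0.53. Hmga2-ps1, Nr4a3, Tmem45b, Aqp4 (a water channel), Cdo1 (cysteine dioxygenase), Igfbp5, Actg2, Slc38a4 and Lonrf3 fell, with differences from -1.34 to -0.85. Other probe sets above the filter gave -1.17 and -0.12 for Aqp4, -0.24 for Slc38a4 and -2.07 for Igfbp5, and for Fbxo32 0.31 and 0.96. Among genes fixed in advance, Hmox1, which degrades heme, rose by 0.82 ± 0.17 and the fatty acid transporter Cd36 by 0.39 ± 0.08. The desaturase Scd1 (-0.83 ± 0.16) and the cell cycle inhibitor Cdkn1a (-0.61 ± 0.12) fell. Pdk4 (0.25 ± 0.08, adjusted p = 0.165), Trim63 (0.22 ± 0.09, adjusted p = 0.252), Ucp3 (0.13 ± 0.08, adjusted p = 0.475) and Alas1, the first enzyme of heme synthesis (-0.29 ± 0.08, adjusted p = 0.0893), did not pass. Fth1, Slc2a4, Mt2, Myh7 and Myh4 lay between -0.08 and 0.01, also without passing, and Fgf21 was not above the signal filter. Pdk4 signals ran from 33192 to 46480 and those of Fth1 from 45382 to 48042. Whether such bright signals still track transcript level was not tested.

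In the additive limma fit, 278 of 11526 genes passed an adjusted p of 0.05, 172 higher and 106 lower after 24 h. All 278 had the same sign in the 3 diets. Of these, 44 were at least 1.5-fold apart in every diet. Without regard to the test, 64 genes were at least 1.5-fold apart the same way in all 3 diets (36 higher, 28 lower) and 50 in mixed directions, where chance signs would give mixed directions 3 times as often. Of the 11526 genes, 2039 had an unadjusted p under 0.05. The limma count was 0 with no filter on signal (2026 at an unadjusted p under 0.05), 0 without the intensity trend (1639 unadjusted), 18 with the probe sets of a gene averaged and 60 without diet in the model. The count of 64 was 42 with a pseudocount in place of the floor (16 mixed) and 45 with the filter at the 65th percentile (5 mixed). Leaving out pools gave 455 without the Control pool at 4 h, 452 without the Control pool at 24 h, and 59 without either HF+SFC+ALA pool.

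**Figure D1:**
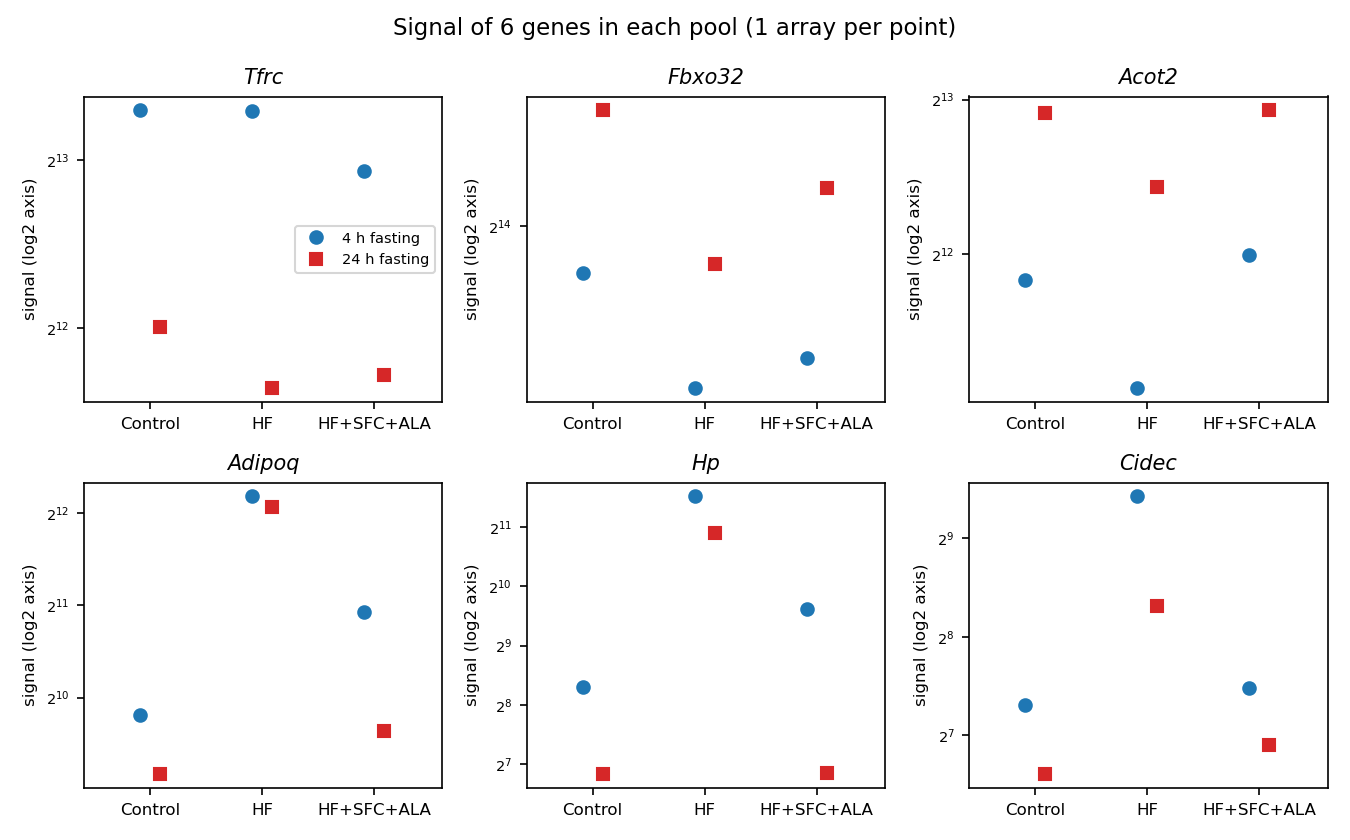
Signal of 6 genes in each of the 6 pools on a log2 axis, in arbitrary array units, by diet and fasting time; each point is 1 array and there are no error bars because no combination had replicates. Tfrc lies lower and Fbxo32 and Acot2 higher at 24 h in all 3 diets, and Adipoq is 4637 and 4280.0 in the HF pools against 901 and 577 in the Control pools at 4 h and 24 h.

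Several genes of fatty acid use rose after 24 h of fasting. Of 23 measured genes of fatty acid oxidation, 4 rose (Acot1, Acot2, Cd36 and Mlycd, malonyl-CoA decarboxylase, at 0.49 ± 0.08), 19 did not pass, and 9 rose when adjusted over the list alone. The targets of PPAR nuclear receptors shared 2 of these, and 3 of 16 rose (6 adjusted over the list alone), with Angptl4, an inhibitor of lipoprotein lipase, at 0.66 ± 0.13. Among 24 muscle atrophy genes 6 rose and none fell (10 and 1 adjusted over the list alone). Among them were Fbxo32, the growth arrest gene Gadd45a (0.81 ± 0.08) and the translation inhibitor Eif4ebp1 (0.78 ± 0.13). Nmrk2 stood at -1.63 ± 0.37 without passing (adjusted p = 0.0581). Antioxidant genes had 2 of 20 higher, Hmox1 and the catalase gene Cat (0.54 ± 0.07), and 6 adjusted over the list alone. Collagen and matrix genes had 3 of 24 lower, Col1a1 (-0.62 ± 0.09), Col6a2 (-0.57 ± 0.10) and Col5a2 (-0.48 ± 0.10), with 10 lower and 1 higher adjusted over the list alone. Smooth muscle markers fell in 2 of 10 (Acta2, -0.47 ± 0.07, and Tagln, -0.42 ± 0.08; 2 adjusted over the list alone), and the lymphocyte markers in 1 of 3 (Ighm, -0.57 ± 0.10; 2 adjusted over the list alone). Of 20 genes of branched-chain amino acid breakdown none passed, 3 were higher adjusted over the list alone, and 18 had a positive difference.

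Camera with a preset correlation of 0.01 placed 8 of 37 lists past an adjusted p of 0.05. Higher were fatty acid oxidation (adjusted p = 2.47e-11), PPAR targets (2.41e-05), muscle atrophy (1.23e-05), antioxidant genes (0.000963) and branched-chain amino acid breakdown (0.0332). Lower were collagen and matrix (1.23e-05), lymphocyte markers (0.0317) and smooth muscle markers (0.0413). None of the 8 passed otherwise: adjusted p = 0.885 with an estimated correlation for branched-chain amino acid breakdown, and adjusted p = 0.84 with an estimated correlation for the other 7. Fry, a rotation test of whether a list moves 1 way, also passed 0 lists. The number of lists was 16 without the HF pool at 4 h and 15 without the HF pool at 24 h. Branched-chain amino acid breakdown no longer passed without any 1 of the Control and HF pools (adjusted p from 0.0808 to 0.218), nor smooth muscle without any 1 of the Control and HF+SFC+ALA pools (0.0808 to 0.114). The same held for lymphocyte markers without either HF+SFC+ALA pool (0.154 and 0.159) and antioxidant genes without the HF pool at 24 h (adjusted p = 0.0525). Between single pools the medians in Control, HF and HF+SFC+ALA were 0.25, 0.37 and 0.05 for fatty acid oxidation, 0.21, 0.45 and 0.03 for PPAR targets, 0.30, 0.08 and 0.13 for atrophy and 0.16, 0.28 and 0.04 for antioxidant genes. They were 0.10, 0.21 and 0.02 for branched-chain amino acid breakdown, -0.40, -0.06 and -0.36 for collagen and matrix, -0.32, -0.72 and -1.06 for lymphocyte markers and -0.20, 0.02 and -0.20 for smooth muscle, beside -0.17, 0.64 and -0.40 for slow fibre genes. Of the other splits of the pools into 3 and 3, 6 of the 9 gave at least as many lists. Diet stayed in the model, so a split that holds both pools of a diet together rests on the real fasting pair of another diet. Such splits are no reference without effects. Splits that part the pools of every diet, but cross the fasting times, gave 15, 17 and 0 lists against 8. The preset test thus ranks lists and does not by itself show a response to fasting. Of 11 adipocyte markers 1 rose, the lipase gene Pnpla2 (0.49 ± 0.08), with 3 higher and 4 lower adjusted over the list alone. These markers gave a median of -0.26 (adjusted p = 0.383), slow fibre genes 0.00 (adjusted p = 0.728) and macrophage markers -0.06 (adjusted p = 0.24) in the same comparison.

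High-fat feeding was then compared with the Control diet over both fasting times. Lep, the hormone leptin, rose at least 13.4-fold (3.74 ± 0.30, adjusted p = 0.00275, the Control pool at 24 h being at the floor), Adipoq, the adipocyte hormone adiponectin, 6.18-fold (2.63 ± 0.21, adjusted p = 0.00275), and Hp 12.5-fold (3.65 ± 0.38, adjusted p = 0.00652). Cidec, a lipid droplet protein, rose 3.76-fold (1.91 ± 0.22, adjusted p = 0.00741) and G0s2, an inhibitor of lipolysis, 3.08-fold (1.62 ± 0.17, adjusted p = 0.00652). Fbxo32 fell 1.67-fold (-0.74 ± 0.09, adjusted p = 0.00741) and the growth arrest gene Gadd45a 1.90-fold (-0.93 ± 0.09, adjusted p = 0.00652). Tmem45b, BC048679, Serpinb1a, Cdo1 and Mybph also rose, by 1.58 to 2.16. D930048N14Rik and Acp5 rose at least 4.65-fold and at least 4.24-fold against Control pools at the floor (both pools and the 24 h pool). Wdr48, 2410006H16Rik, Arrdc3, Spns2, Kpnb1, Ppp1r15a, Pfkfb3, Syne1, Abcf3, Car14 and Arrdc2 fell, with differences from -1.47 to -0.86. Other probe sets above the signal filter gave -0.32 and 0.09 for Wdr48, -0.18 to -0.10 for Kpnb1 (3 probe sets) and -0.19 for Abcf3, and for Tfrc, which did not pass, -0.56 and 0.28. Of the genes fixed in advance, Ucp3 (-0.48 ± 0.10, adjusted p = 0.0695), Trim63 (-0.40 ± 0.11, adjusted p = 0.158), Scd1 (0.69 ± 0.20, adjusted p = 0.169), Mt2 (0.62 ± 0.15, adjusted p = 0.104), Cd36 (0.32 ± 0.10, adjusted p = 0.201), Cdkn1a (-0.45 ± 0.14), Hmox1 (-0.55 ± 0.21), Ppargc1a (0.31 ± 0.21), Alas1 (-0.20 ± 0.09), Tfrc (-0.18 ± 0.11), Pdk4 (-0.15 ± 0.10), Slc2a4 (-0.11 ± 0.09), Fth1 (0.02 ± 0.08), Myh7 (-0.08 ± 0.23) and Myh4 (-0.04 ± 0.09) did not pass.

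In the limma fit 102 of 11526 genes passed, 65 higher and 37 lower in HF, all with the same sign at both fasting times and 67 at least 1.5-fold apart at both. Without the test, 256 genes were at least 1.5-fold apart the same way at both times (180 higher, 76 lower) and 110 in opposite ways, which chance would give equally often. Across genes the difference at 4 h correlated with that at 24 h at r = 0.22 (Spearman's rho 0.24). An unadjusted p under 0.05 was reached by 1692 genes. The limma count was 0 with no filter on signal (1993 at an unadjusted p under 0.05) and 0 without the intensity trend (1348 unadjusted), and averaging the probe sets left 1 gene (Lep). The count of 256 was 109 with the filter at the 65th percentile, where 11 genes went in opposite ways. Leaving out pools gave 592 without the Control pool at 4 h, 279 without the Control pool at 24 h, 275 without the HF pool at 4 h, 47 without the HF pool at 24 h, and 58 and 59 without the HF+SFC+ALA pools at 4 h and 24 h.

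Some markers of adipocytes and of connective tissue rose with high-fat feeding. Of 11 measured adipocyte markers 3 rose (Lep, Adipoq and Cidec), 8 did not pass, and adjusted over the list alone 6 were higher and 1 lower. Retn, the hormone resistin, stood at 2.17 ± 0.49 (adjusted p = 0.0896). Among 24 collagen and matrix genes 6 rose (17 adjusted over the list alone), including Col3a1 (0.93 ± 0.14), Col5a2 (0.85 ± 0.13) and Col1a1 (0.82 ± 0.11). Fibroblast markers, 4 of which stand in other lists, had 3 of 11 higher (6 adjusted over the list alone), with Dpt at 0.53 ± 0.10. Tendon markers had 3 of 8 higher (6 adjusted over the list alone), with Tnmd at 0.84 ± 0.10 and Fmod at 0.57 ± 0.08. All 16 macrophage markers had positive differences, led by Mrc1 (0.97 ± 0.20, adjusted p = 0.0714) and C1qb (0.87 ± 0.20, adjusted p = 0.099). None passed over all genes and 6 were higher adjusted over the list alone. Smooth muscle markers had 1 of 10 higher (Tagln, 0.51 ± 0.09; 1 adjusted over the list alone), and 0 of 7 Schwann cell markers and 0 of 4 brown adipocyte markers passed (2 and 2 adjusted over the list alone). Circulating muscle factors rose in 2 of 12, Fstl1 (0.83 ± 0.12) and Sparc (0.63 ± 0.08), with 3 adjusted over the list alone. Their median was -0.04 at 4 h (5 of 12 positive) and 0.60 at 24 h (10 of 12 positive), so the higher list rests on the 24 h pair. Heat shock genes rose in 1 of 19, Hspa1b (1.45 ± 0.18), with 4 adjusted over the list alone.

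The members of 3 muscle and metabolic lists that passed in this comparison fell. Of 24 atrophy genes 2 fell (Gadd45a and Fbxo32), with 9 lower and 1 higher adjusted over the list alone. Of 20 antioxidant genes 2 fell, Gpx3 (-0.67 ± 0.11) and Gstm1 (-0.59 ± 0.10), with 4 adjusted over the list alone. In the fatty acid oxidation list Acot2 fell (-0.59 ± 0.10) although 18 of 23 members had positive differences, among them Decr1 (0.54 ± 0.10, adjusted p = 0.0537) and Fabp3 (0.48 ± 0.11, adjusted p = 0.0995). In that list 9 were higher and 2 lower adjusted over the list alone. Insulin signalling genes had 15 of 17 negative differences and branched-chain amino acid genes 17 of 20, with 0 passing in either (1 higher and 4 lower, and 4 lower, adjusted over the list alone).

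Camera with the preset correlation passed 15 of 37 lists for HF against Control. Higher were collagen and matrix (adjusted p = 3.44e-17), macrophage, fibroblast and tendon markers (6.32e-07 each), adipocyte markers (1.47e-05), fatty acid oxidation (9.03e-05), smooth muscle (0.00897), Schwann cell (0.0104), heat shock (0.0185), brown adipocyte (0.0381) and circulating muscle factors (0.0396). Lower were atrophy (3.02e-05), branched-chain amino acid breakdown (0.000502), insulin signalling (0.00611) and antioxidant genes (0.0463). Otherwise 0 passed: adjusted p = 0.688 with an estimated correlation for the collagen, adipocyte, fibroblast, Schwann cell and tendon lists. It gave adjusted p = 0.86 for antioxidant genes and adjusted p = 0.784 for the other 9. Fry passed 0 lists, and the preset test passed 9 without the Control pool at 24 h. Without the Control pool at 4 h fatty acid oxidation (adjusted p = 0.0592), antioxidant genes (0.0546) and Schwann cell markers (0.0546) did not pass. Without the HF pool at 4 h insulin signalling (0.0872), antioxidant genes (0.496), branched-chain amino acid breakdown (0.0870) and Schwann cell markers (0.0861) did not. Without the Control pool at 24 h these were insulin signalling (0.184), antioxidant genes (0.0559), circulating factors (0.219), brown adipocyte (0.171), smooth muscle (0.154) and Schwann cell markers (0.0750). Without the HF pool at 24 h they were heat shock (0.356), circulating factors (0.853), brown adipocyte (0.573) and smooth muscle (0.241). The medians at 4 h and 24 h were 0.34 and 0.70 for collagen and matrix, 0.36 and 0.70 for macrophage, 0.18 and 0.47 for fibroblast, 0.37 and 0.60 for tendon and 0.90 and 0.47 for adipocyte markers. They were 0.13 and 0.24 for fatty acid oxidation, 0.08 and 0.30 for smooth muscle, 0.31 and 0.24 for Schwann cell, 0.05 and 0.17 for heat shock and 0.11 and 0.77 for brown adipocyte lists. The lower lists had -0.07 and -0.35 for atrophy, -0.24 and -0.13 for branched-chain amino acid breakdown, -0.19 and -0.21 for insulin signalling and -0.10 and -0.04 for antioxidant genes.

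The third comparison added SFC and ALA to the high-fat diet. No gene passed the test, and several of the genes farthest apart, such as Hp, Lep and Adipoq, were also among the highest in HF against Control. Hp was 7.92-fold lower in HF+SFC+ALA than in HF (-2.99 ± 0.38, adjusted p = 0.0562), Adipoq 3.58-fold (-1.84 ± 0.21, adjusted p = 0.0562) and Cidec 3.20-fold (-1.68 ± 0.22, adjusted p = 0.0562). Lep stood at -1.99 ± 0.30 (adjusted p = 0.0775). The Hp signal was 783 and 115 in the HF+SFC+ALA pools at 4 h and 24 h, against 2940.3 and 1921 in HF and 317 and 114 in Control. Cdo1, Tmem45b, Rbp4 (a retinol carrier), Sncg, Wfdc21, Six5, LOC102631979 and Aldh1a7 were lower at both fasting times, with differences from -1.82 to -1.23 and adjusted p from 0.0772 to 0.761. Higher at both times were Wdr48 (1.10 ± 0.16, adjusted p = 0.0772; its 2 other probe sets above the filter gave -0.35 and 0.06) and 11 others, Gsdmcl2, Il1r1, Plk5, Ogg1, Pnpla1, Kif18a, Smpd5, Tkfc, Mgat3, Crhr1 and Mir670hg, at 0.90 to 1.94 with adjusted p from 0.346 to 0.928. Of the genes fixed in advance, Ucp3 (0.42 ± 0.10), Fbxo32 (0.29 ± 0.09), Scd1 (-0.76 ± 0.20), Mt2 (-0.61 ± 0.15), Ppargc1a (-0.33 ± 0.21), Cdkn1a (-0.25 ± 0.14), Pdk4 (0.16 ± 0.10), Trim63 (0.11 ± 0.11), Cd36 (0.10 ± 0.10), Tfrc (-0.14 ± 0.11), Hmox1 (-0.10 ± 0.21), Myh4 (-0.07 ± 0.09), Myh7 (0.06 ± 0.23), Fth1 (-0.03 ± 0.08), Alas1 (-0.02 ± 0.09) and Slc2a4 (0.01 ± 0.09) had adjusted p from 0.449 to 0.997. The other probe set of Alas1 gave -0.69, that of Ogg1 0.59, and the other probe sets of Tfrc, at 0.071 to 0.35, had the opposite sign.

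Limma called 0 of 11526 genes for HF+SFC+ALA against HF, with 585 at an unadjusted p under 0.05, and no other tool was run on single genes. Without the test, 114 genes were at least 1.5-fold apart the same way at both fasting times (41 higher, 73 lower) and 90 in opposite ways. Across genes the differences at 4 h and 24 h correlated at r = 0.053 (Spearman's rho 0.030). The limma count was 6 with the filter at the 65th percentile (Adipoq, Cidec, Hp, Ifi27l2a and Tuba1a lower, Igf1 higher, adjusted p = 0.0381 for each, named here after their values were seen). The count of 114 was 25 there (15 in opposite ways) and 65 with a pseudocount (29 in opposite ways). Leaving out pools gave 107 without the Control pool at 4 h, 109 without the Control pool at 24 h, 4 without the HF pool at 4 h (Adipoq, Hp, Ifi27l2a and Irak1) and 2 without the HF+SFC+ALA pool at 4 h (Adipoq and Hp), all chosen after their values were seen. Over the 11526 genes, pools simulated without effects gave up to 15 calls for this comparison in 100 simulations. With spreads drawn from the prior they gave up to 1 in 20 draws.

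None of the measured members of any list passed between HF+SFC+ALA and HF. Adipocyte markers were negative in 9 of 11 (median -0.72; 3 lower adjusted over the list alone), collagen and matrix genes in 22 of 24 (median -0.26; 4 adjusted over the list alone). So were fibroblast markers in 10 of 11 (2 adjusted over the list alone) and Schwann cell markers in 7 of 7 (2 adjusted over the list alone), with Mbp, a myelin protein, at -0.56 ± 0.10 (adjusted p = 0.158). Smooth muscle markers were negative in 8 of 10 (2 adjusted over the list alone), lipogenesis genes in 16 of 21 (0 adjusted over the list alone) and immediate early genes in 17 of 22 (1 adjusted over the list alone), with Fos at -0.43 ± 0.16. PPAR targets were positive in 14 of 16 (2 adjusted over the list alone), with Acot1 at 0.82 ± 0.26 (adjusted p = 0.778) and Acot2 at 0.68 ± 0.10 (adjusted p = 0.0772), and fatty acid oxidation in 21 of 23 (1 adjusted over the list alone). These counts are over both fasting times, and the single times differed. PPAR targets had a median of 0.37 at 4 h (15 of 16 positive) and -0.04 at 24 h (6 of 16 positive), and fatty acid oxidation 0.22 (21 of 23 positive) and -0.08 (7 of 23 positive), beside slow fibre medians of 0.53 and -0.39. Fibroblast markers had 0.07 at 4 h (6 of 11 positive) and -0.34 at 24 h (0 positive), and collagen and matrix genes -0.06 (9 of 24 positive) and -0.41 (2 of 24 positive), so both lower lists rest on the 24 h pair. Adipocyte markers had -0.38 and -0.18, Schwann cell markers -0.41 and -0.35, smooth muscle -0.04 and -0.23, lipogenesis -0.12 and -0.14 and immediate early genes -0.21 and -0.09. Camera with the preset correlation passed these 9 lists of 37, with adjusted p = 7.43e-08 for collagen, 1.01e-05 for adipocyte, 5.23e-05 for PPAR targets, 0.000183 for Schwann cell, 0.00048 for fibroblast, 0.00105 for smooth muscle and fatty acid oxidation, 0.00187 for lipogenesis and 0.00692 for immediate early genes. Otherwise 0 passed: adjusted p = 0.713 with an estimated correlation for 7 of them, adjusted p = 0.73 for PPAR targets and adjusted p = 0.97 for fatty acid oxidation. Fry passed 0. The preset test passed 16 lists without the HF pool at 4 h, 19 without the HF pool at 24 h and 18 without the HF+SFC+ALA pool at 24 h, and the fatty acid oxidation list turned negative without the HF+SFC+ALA pool at 4 h (median -0.056, adjusted p = 0.645). Its median was also negative without the HF pool at 4 h (-0.064, adjusted p = 0.965). PPAR targets (medians of -0.034 and -0.047, adjusted p = 0.361 and 0.417) and immediate early genes (adjusted p = 0.604 and 0.307) did not pass without the HF or the HF+SFC+ALA pool at 4 h. Without the HF pool at 24 h lipogenesis (adjusted p = 0.132), collagen (0.0967), smooth muscle (0.267) and fibroblast markers (median 0.036, adjusted p = 0.308) did not, nor fibroblast markers without the HF+SFC+ALA pool at 24 h (adjusted p = 0.130).

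Heme, iron and mitochondrial genes were the groups closest to the question of the series. Of 12 heme synthesis genes 0 passed in any of the 3 comparisons, while adjusted over the list alone 1 was lower with fasting and 1 higher with HF. For HF+SFC+ALA against HF their differences ran from -0.26 to 0.28 (median 0.015, adjusted p = 0.789; 0 adjusted over the list alone). That range takes 1 probe set per gene, and the other probe set of Alas1, given above for this comparison, lay below it. The median of the 12 genes was 0.095 at 4 h (9 of 12 positive, 94.4th percentile of random lists) and -0.024 at 24 h (5 of 12 positive, 34.4th percentile). With fasting it was 0.029 in Control, -0.0082 in HF and -0.13 in HF+SFC+ALA (1 of 12 positive, 3.06th percentile). Of 20 genes of heme breakdown and iron handling only Tfrc (lower) and Hmox1 (higher) passed, both with fasting, with 2 higher and 1 lower adjusted over the list alone. The list gave a median of -0.02 for HF+SFC+ALA against HF (adjusted p = 0.866), although its mean (0.0055) and its test had the opposite sign. The 32 complex I genes had medians of 0.0075, 0.010 and -0.00083 with fasting, HF and HF+SFC+ALA, and the lists for complexes II and III, IV, V and the TCA cycle passed in none of these (lowest adjusted p = 0.137, for the TCA cycle under HF+SFC+ALA). Within a fasting time the medians of these lists lay on the same side of 0 as that of the slow fibre genes. For HF against Control at 4 h complex V (-0.040) and complex IV (-0.060) stood at the 57.8th and 29.2nd percentile of random lists, and for HF+SFC+ALA against HF at 24 h the TCA cycle (-0.071) at the 16.9th. For HF+SFC+ALA against HF, the complex I median was 0.13 at 4 h and -0.12 at 24 h, while the slow fibre median was 0.53 and -0.39. For HF against Control the complex I median was -0.08 and 0.06, and the slow fibre median -0.44 and 0.45. Over both times the slow fibre list stood at -0.03 for HF and 0.04 for HF+SFC+ALA (adjusted p = 0.605 and 0.866), and for HF its mean (0.10) and test had the opposite sign to its median.

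**Figure D2:**
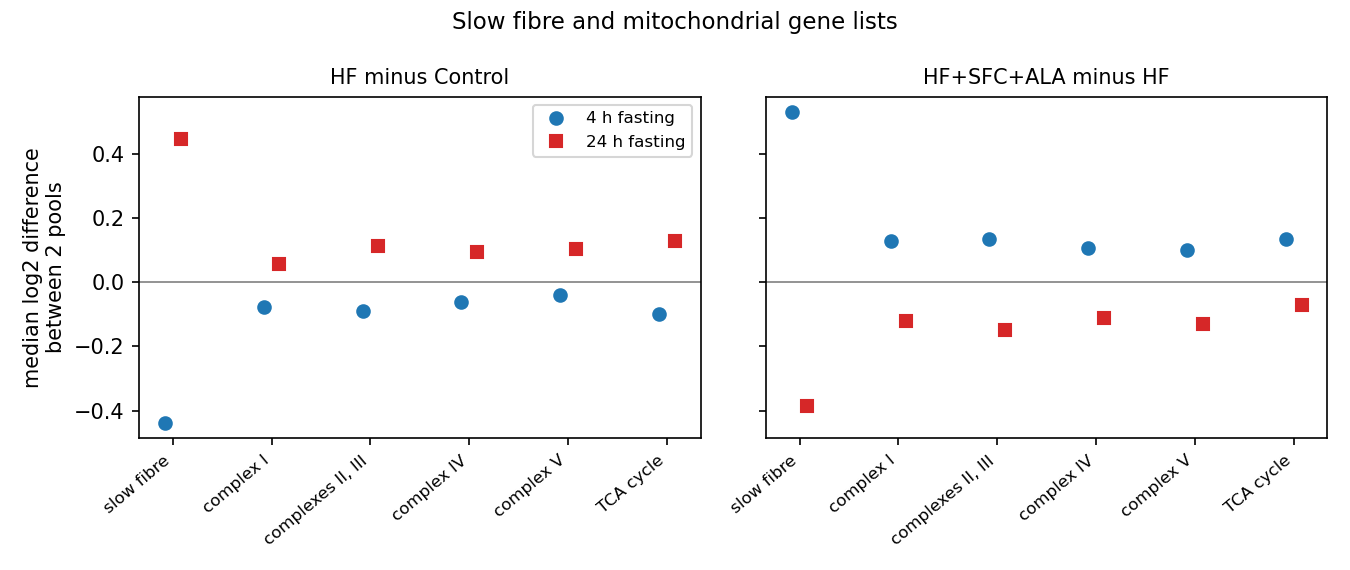
Median log2 difference between 2 pools of the slow fibre list and 5 mitochondrial lists, for HF minus Control and for HF+SFC+ALA minus HF at each fasting time; each point is the median of a list over a single pair of arrays, without error bars because no combination had replicates. All 6 lists lie on opposite sides of 0 at 4 h and 24 h, the slow fibre list at -0.44 and 0.45 in the first panel and at 0.53 and -0.39 in the other.

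Against Control, the HF+SFC+ALA diet had 4 genes past the threshold, all higher. BC048679 stood 4.15-fold higher (2.05 ± 0.22), G0s2 2.82-fold (SE 0.17 on the log2 scale), Tm6sf1 2.31-fold (1.21 ± 0.13) and Aspn, a matrix protein, 1.98-fold (0.98 ± 0.11), each with adjusted p = 0.0278. In 100 simulations of pools without effects this comparison gave at least 1 call in 62 and up to 14, so a count of 4 lies within what these simulations gave. With spreads drawn from the prior, fasting, HF against Control and HF+SFC+ALA against HF gave at most 2, 0 and 1 calls in 20 draws. Whether 4 exceeds what no effect gives therefore depends on the spread assumed. The 4 genes are named because the count is small, after their values were seen. All 4 also passed for HF against Control, where independent lists of these sizes would share 0.0354 genes. Pools simulated without effects shared 0.26 genes on average and up to 4 in 100 simulations, so part or all of the overlap may come from the Control pools that both comparisons share. An unadjusted p under 0.05 was reached by 1426 genes, and 183 genes were at least 1.5-fold apart the same way at both times (122 higher, 61 lower) against 108 in opposite ways. The limma count of 4 was 0 with quantile normalization (1438 at an unadjusted p under 0.05), no filter on signal (1770), averaged probe sets (1095) or no intensity trend (1076). The count of 183 was 53 with the filter at the 65th percentile (11 in opposite ways) and 85 with a pseudocount (50 in opposite ways). Leaving out pools gave 435 and 101 without the Control pools at 4 h and 24 h, 88 without either HF pool, and 0 without the HF+SFC+ALA pool at 4 h (761 unadjusted).

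Whether HF+SFC+ALA moved genes against the direction of the high-fat diet was examined with arrays that the comparisons do not share. Of the 102 genes called for HF, 97 had the opposite sign in HF+SFC+ALA minus HF and 83 did so at both times, but these share the HF arrays. Within a fasting time the correlation across all genes was -0.51 at 4 h and -0.55 at 24 h, where pools without effects gave -0.50 and -0.50 in simulation. The covariances were -0.0640 and -0.0833 against simulated -0.0466 and -0.0469. Without a shared array, HF minus Control at 4 h correlated with HF+SFC+ALA minus HF at 24 h at r = -0.14 (Spearman's rho -0.10, covariance -0.0177, simulated 2.91e-05), and the reverse pairing gave r = -0.011 (rho 0.035, covariance -0.00157, simulated 7.78e-05). With the filter at the 65th percentile these were -0.191 and 0.00855. The simulations draw genes independently, whereas genes move together between pools. Over the 45 pairings of array differences that share no array, which hold these 2 and the effects of diet and fasting, the median size of r was 0.12 and the 95th percentile 0.239. Of 1097 genes at least 1.5-fold apart in HF minus Control at 4 h, 58.4% had the opposite sign in the disjoint pools (simulated 49.9%), and of 1514 at 24 h 49.6% (simulated 49.6%).

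The fasting response was also compared between diets as values without a test, since each diet had 1 pool per time. At least 2-fold apart between 24 h and 4 h were 335 genes in Control, 248 in HF and 205 in HF+SFC+ALA. These were 80, 57 and 29 with the filter at the 65th percentile, 172, 117 and 93 with a pseudocount, and 207 in Control and 127 in HF+SFC+ALA with probe sets averaged. Across genes the response in HF had a slope of 0.145 on that in Control and the response in HF+SFC+ALA 0.208, with correlations of 0.16 and 0.24. These slopes were 0.297 and 0.378 with the filter at the 65th percentile. Noise in the single Control pair lowers both slopes, so they do not measure the relative size of the response. The SD of the response over genes was 0.41 in Control, 0.38 in HF and 0.35 in HF+SFC+ALA. Over the 278 genes called for fasting, the median size of the response was 0.60 in Control, 0.52 in HF and 0.49 in HF+SFC+ALA on the log2 scale. Between diets at a single time, 266 and 420 genes were at least 2-fold apart for HF against Control at 4 h and 24 h, and 207 and 232 for HF+SFC+ALA against HF. The strict filter lowered these to 57, 118, 26 and 31 and a pseudocount to 126, 239, 101 and 91. Averaged probe sets gave 175 and 132 for the 4 h pairs.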

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

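The tests of slow fibre share and of array scaling were chosen only after the result was seen.

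Slow fibre genes differed between pools in opposite directions, and these differences stood out because 1 group moved one way and the other the opposite way; none of them was tested. The median fasting response of the 14 slow fibre genes was 0.64 in HF and -0.40 in HF+SFC+ALA, a difference of -1.03. For HF minus Control it was -0.44 at 4 h and 0.45 at 24 h, a difference of 0.883, and for HF+SFC+ALA minus HF it was 0.53 and -0.39, a difference of -0.916. Myh7, the slow myosin heavy chain, stood at 0.71 and -0.59 in HF+SFC+ALA minus HF, a difference of -1.30. These differences are not separate observations. The -1.03, the -0.916 and the Myh7 value rest on the same HF and HF+SFC+ALA arrays, and the 0.883 uses the same HF arrays.

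The deposited values hold no shift of all genes alike of this size, since the median of all genes was at most 0.0385 of the slow fibre median over the 4 diet pairs. The arrays had already been scaled to a common level, which keeps that median small. This outcome was therefore largely set beforehand and decides nothing further. The value does not bear on a shift that depends on signal. A different share of slow fibres in each pool and a response of these genes to diet and fasting time cannot be told apart, because each combination had 1 pool. That 11 of 14 slow fibre genes followed the signs of the list's medians over these pairs decides nothing, since the members' signs in the single pairs alone require at least 10. In these diet pairs the 16 fast fibre genes had medians on the same side as the slow ones (-0.12 and 0.02 for HF minus Control at 4 h and 24 h, 0.10 and -0.18 for HF+SFC+ALA minus HF). The value of 0.02 lay at the 67.4th percentile of random lists, which is no clear shift. With fasting in Control the slow and fast medians lay on opposite sides, at -0.17 and 0.02. These values do not settle what part a shift between the fibre types has.

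A control probe set for the 3' end of the transferrin receptor transcript, outside the genes compared, gave a signal: its difference between 24 h and 4 h was -1.84 ± 0.191 (SD, n = 3 pairs), with -1.98 in Control, -1.62 in HF and -1.92 in HF+SFC+ALA. The 42 spike-in control probe sets ran from -0.605 to 0.183.

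Probe sets without a single listed gene were also outside the comparisons, and the limma fit called 26 of 2396 for fasting (12 higher, 14 lower) and 1 for HF against Control. For HF+SFC+ALA against HF it called 0, with 95 at an unadjusted p under 0.05. For fasting, the largest differences were 1.32 ± 0.16 and 1.31 ± 0.17 among those higher at 24 h and -1.61 ± 0.22 and -1.33 ± 0.22 among those lower.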

How the results depend on the processing

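The counts without adipocyte markers and at an adjusted p under 0.1 were chosen only after the result was seen. Counts below are in the order fasting, HF against Control, HF+SFC+ALA against HF and HF+SFC+ALA against Control (278, 102, 0 and 4 as reported). Where a count moved, the cause was not tested, except that leaving out a pool leaves 5 arrays and assumes that a lone pool varies like the others. For fasting, and for the contrast between the other diets, leaving out either pool of a diet uses the same arrays. Those values come in near-equal pairs and are not separate checks.

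Quantile normalization gave 240, 84, 0 and 0 genes (604 and 1438 at an unadjusted p under 0.05 in limma for the zeros), sharing 230 of the 278 and 82 of the 102. No filter on signal gave 0 for all 4 (2026, 1993, 1120 and 1770 unadjusted), and so did no trend (1639, 1348, 635 and 1076). The filter at the 65th percentile gave 369, 124, 6 and 5, averaged probe sets 18, 1, 0 and 0 (550 and 1095 unadjusted for the zeros), no floor 234, 99, 0 (582) and 4, and a pseudocount 282, 105, 0 (589) and 4. Without diet in the model fasting gave 60. Without adipocyte markers HF against Control gave 97, and an adjusted p under 0.1 gave 12 for HF+SFC+ALA against HF. Leaving out 1 pool gave 59 to 455, 47 to 592, 0 to 109 and 0 to 435.

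Genes at least 1.5-fold apart the same way numbered 109, 25 and 53 for the diet comparisons with the 65th percentile filter, and 42 for fasting, 65 for HF+SFC+ALA against HF and 85 against Control with a pseudocount. Genes at least 2-fold apart with fasting in Control, HF and HF+SFC+ALA were 80, 57 and 29 with that filter and 172, 117 and 93 with a pseudocount; averaging gave 207 in Control and 127 in HF+SFC+ALA. For HF against Control at 4 h and 24 h they were 57 and 118 with the filter and 126 and 239 with a pseudocount, and for HF+SFC+ALA against HF 26 and 31, and 101 and 91; averaging gave 175 and 132 at 4 h. With the filter the correlations without a shared array were -0.191 and 0.00855 and the slopes on Control 0.297 and 0.378; a pseudocount gave slopes of 0.18 and 0.25.

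With an estimated correlation and with fry, 0 lists passed in any of the 3 comparisons (8, 15 and 9 as reported). Leaving out 1 pool gave 7 to 16, 9 to 19 and 10 to 19 lists. Of 192 values of the lists that passed, 153 kept test direction and side of the threshold, 38 lost the threshold and 1 reversed in test direction. List medians changed sign more often. For HF+SFC+ALA against HF, PPAR targets gave -0.034 and -0.047 without the HF or the HF+SFC+ALA pool at 4 h. Fibroblast markers gave 0.036 without the HF pool at 24 h. For HF against Control, circulating muscle factors gave -0.0086 and -0.074 without the Control or the HF pool at 24 h. Fatty acid oxidation for HF+SFC+ALA against HF reversed to -0.056 (adjusted p = 0.645) without the HF+SFC+ALA pool at 4 h; with 1 pool left out its median ran from -0.0645 (without the HF pool at 4 h) to 0.190. Of 714 values of named genes with 1 pool left out, 580 kept direction and side of the threshold, 78 lost it and 56 gained it; quantile normalization lost 6 of 119, averaging 45 of 110 and a pseudocount 0 of 119. No paired analysis was possible because the labels carry no replicate numbers to pair pools by, beyond the blocks of diet and fasting time already in the fit. Signal near the floor of 26.4 limits folds of dim genes.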

Other observations

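The tests of adipocyte RNA, of the HF arrays shared between contrasts and of genes called in both contrasts were chosen only after the result was seen; the splits of pools and the correlation of HF with the fasting response were chosen before, the other pairings set beside it after.

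Other genes past the threshold with 24 h of fasting belong to lists that did not pass as a whole. Gabarapl1 (0.70 ± 0.13) and Ulk1 (0.62 ± 0.09), which act in autophagosome formation, rose in 2 of 19 autophagy genes (6 adjusted over the list alone), and Ulk1 fell with HF (-0.82 ± 0.12). Chaperone genes fell in 3 of 19, Hsp90aa1 (-0.49 ± 0.06), Dnaja1 (-0.38 ± 0.08) and Hspa8 (-0.32 ± 0.06), with 4 lower and 1 higher adjusted over the list alone. Of 22 immediate early genes Jun (0.72 ± 0.07), Klf2 (0.57 ± 0.11) and Klf4 (0.44 ± 0.09) rose and Nr4a3 and Dusp1 (-0.47 ± 0.07) fell, while with HF Dusp1 rose (0.67 ± 0.08) and Jun fell (-0.57 ± 0.08). Of 24 glycolysis and glycogen genes, Pfkfb3 rose with fasting (0.63 ± 0.11) and fell with HF, and Ppp1r3c, a glycogen-targeting subunit, fell with fasting (-0.80 ± 0.08). Of 21 lipogenesis genes Dgat2 (0.56 ± 0.08) and Gpam (0.48 ± 0.07) rose and Scd1 fell with fasting, and Dgat2 rose with HF (0.55 ± 0.09). Insulin signalling had Foxo3 (0.39 ± 0.08) higher and Irs1 (-0.40 ± 0.06) lower of 17 genes, and regeneration had Gadd45a, Ankrd1 (0.51 ± 0.11) and Myf6 (0.33 ± 0.07) higher and Cdkn1a lower of 18.

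With 24 h of fasting Rsad2 (0.70 ± 0.10) of 18 interferon genes and Herpud1 (0.33 ± 0.07) of 22 integrated stress genes also rose, and Nfil3 (-0.56 ± 0.12) of 17 clock genes, Igf1 (-0.58 ± 0.08) of 12 circulating factors and Cd163 (-0.68 ± 0.15) of 16 macrophage markers fell. Of the 12 circulating factors 1 other passed and rose. None of the 12 endothelial, 16 fast fibre or 19 ribosomal protein genes passed in limma for fasting, HF against Control or HF+SFC+ALA against HF, and 0 did adjusted over the list alone. The measured neutrophil, erythroid and keratinocyte markers, 2 each, had no list test; S100a8 stood at 0.99 ± 0.47 (adjusted p = 0.364) for HF against Control and Hbb-b2 at -0.64 ± 0.33 (adjusted p = 0.97) for HF+SFC+ALA against HF.

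The 3 against 3 splits of the pools number 10, too few for a share under 0.05. For genes 1 of the 10 gave as many as the real 278, with 0 in the highest other. For lists 7 of the 10 gave as many as the real 8, with 17 in the highest other. Because diet stayed in the model, splits that hold both pools of a diet together rest on the real fasting pair of another diet. The counts over the other splits are therefore no reference without effects.

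Genes higher in HF than in Control were often lower again in HF+SFC+ALA; for the adipocyte markers themselves more adipocyte RNA in the HF pools may account for the pattern, since 8 of 11 followed it at both times, against a median of 1 in random lists. For 62 genes outside that list it cannot be told apart from other causes: they kept a median of 48.1% of their HF excess at 4 h (bootstrap 37.3 to 66.8) and 36.6% at 24 h (27.8 to 45.0). The adipocyte markers at least 1.5-fold higher in HF kept -31.5% to 58.6% at 4 h and 5.93% (Adipoq) to 96.8% (Slc36a2) at 24 h. Most markers kept less than these medians: all but Trarg1 kept at most 33.5% at 4 h, and all but Slc36a2 at most 36.9% (Retn) at 24 h. Chance values of the shared HF arrays cannot be told apart from an effect of the diet, because of the correlations without a shared array 1 was near 0 (-0.0107) and the other was not (-0.138).

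Differences with HF tended to oppose those with fasting: of 28 genes called in both, 26 went opposite ways, and Dgat2 and Smox the same way, where independent lists would share 2.46 genes (pools simulated without effects shared 2 at most in 100 simulations, but give too few calls to bear on this count). Without 1 pool the opposite genes were 70 of 110 (Control at 4 h), 76 of 78 (HF at 4 h), 7 of 8 (HF+SFC+ALA at 4 h), 70 of 79 (Control at 24 h), 14 of 15 (HF at 24 h) and 6 of 7 (HF+SFC+ALA at 24 h), and over wider sets the share was smaller: 199 of the 278 genes called for fasting, 74 of the 102 called for HF, and 55.7% at 4 h and 57.4% at 24 h of the 970 genes at least 1.5-fold apart with fasting in HF+SFC+ALA. Single arrays that both comparisons share cannot be told apart from an opposing effect of diet: with the fasting response of HF+SFC+ALA, which shares no array, HF minus Control correlated at -0.0873 at 4 h and -0.146 at 24 h, below the bound of -0.05 set in advance, but that bound left out how much such values vary between pools. Pools simulated without effects gave -0.0319 to 0.0566 at 4 h and -0.0381 to 0.0368 at 24 h, but with genes drawn independently. The 4 other pairings of a diet difference with the fasting response of the remaining diet, also without a shared array, gave 0.0286 to 0.102. Of these, HF+SFC+ALA minus HF with the Control response (0.0286 and 0.102) holds HF with a minus sign. Those values do not count against an opposing effect. HF+SFC+ALA minus Control with the HF response gave 0.0647 and 0.0545. With 1 pool per combination there is no observed reference without effects. Whether genes of low spread add to the 26 cannot be told either, because these genes move together (a first direction held 67.9% of their variance, against 66.3% at the 95th percentile for independent genes).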
